A study of Homo sapiens with 4 samples.

How the data were processed

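Gene expression was measured in Kelly cells, an established human neuroblastoma line with amplified MYCN and an activated ALK receptor. The cells studied were a derivative resistant to TAE684, an inhibitor of the ALK kinase, and were kept in 1 µM of it. Per the labels' protocols, cells were exposed for 24 h to virus carrying a hairpin against BORIS (shBORIS) or against luciferase (shLUC, the control), and surviving cells were selected in puromycin for 48 h. BORIS is the protein made by CTCFL, a paralog of the genome-organising factor CTCF that is normally restricted to the germ line. The labels describe the 2 arrays of each hairpin as biological duplicates, so p-values measure the spread between those duplicates.

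Per the labels' protocols, synthetic ERCC RNAs were added to the total RNA, 100 ng was labelled with biotin, and the product was hybridised to an Affymetrix PrimeView array, which carries several probe sets for many genes. The deposited values are probe set intensities on a linear scale, 1 column per array, with no pooling of replicates. MAS5, R 3.1.3 and affy are named in the submitters' processing notes, without the role of each. The step that set the 4 arrays on a common scale is not given in the sources used here. From the values, the ERCC probe sets had median intensities of 25.5, 25.8, 24.8 and 24.4 on shBORIS replicates 1 and 2 and shLUC replicates 1 and 2, while the median of all cellular probe sets was 80.8, 84.5, 64.4 and 60.4. The scale of the deposited intensities therefore looks set by the spike-ins, but no label states it. If so, values as deposited compare RNA with the amount of spike-in, and the amount of spike-in per cell is not given in the sources used here.

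The table held 49495 probe sets. The 202 control probe sets, of which 102 were Affymetrix controls and 100 were ERCC, were left out of all tests of genes. Of the other 49293, 45278 had 1 gene symbol in the platform's annotation, 1333 had several and were left out, and 2682 were not in the annotation table and stayed unnamed. Symbols were updated through the Entrez identifier, which was found in the reference gene table (GRCh38.p14) for 45208 of the single-symbol probe sets and not for 70. Each of the 18244 genes was represented by its probe set with the highest mean over the 4 arrays. Genes with a mean under the 40th percentile, at an intensity of 61.4, were left out, which left 10946 genes tested and 7298 untested. Probes for near-identical paralogs and for overlapping genes cannot be told apart on such arrays, and genes for which this applies are named as uncertain.

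Values were taken as log2(intensity + 16), so fold changes of dim genes are understated. A linear model with the hairpin as the only term was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance and 2 residual degrees of freedom. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The deposited values were used without further normalization for this fit. Because the median gene differed between the groups, the same model was also fitted after subtracting each array's median over the genes tested, and values from that fit are called relative to the median gene. All adjusted p-values of single genes are from limma. Those of single CTCFL probe sets other than the brightest are from the same model fitted to all cellular probe sets. As deposited, limma gave the prior infinite degrees of freedom, so each gene's variance is the fitted trend's and the smallest p-values are not to be read literally; on centred arrays the prior had 7.86 degrees of freedom. An exact permutation test of 2 arrays against 2 cannot give a two-sided p under 0.333, so a p-value of a single gene rests on the spread that limma pools over genes.

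A set of 28 gene lists was fixed before the data were examined. They covered the cell cycle, CTCF and cohesin, neuroblastoma cell states, signalling, stress, metabolism, ribosomal proteins, germ-line antigens, imprinted and HOX genes, and markers of other cell types. They were tested with camera at its preset correlation of 0.01, which compares a list with the other genes tested, and the p-values were adjusted over the 28 lists. Camera with a correlation estimated from the data and fry, which asks whether a list moves on balance one way, were run beside it. With an estimated correlation camera takes its p from 2 residual degrees of freedom, so a list that fails it is not thereby shown unchanged. Medians of lists were also set against 10000 random lists of genes of the same mean level.

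The genes to be named were fixed by a rule before the data were examined. The rule took CTCFL, the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap between groups, up to 4 members of each list with the smallest p as deposited, and MYCN, ALK, CTCF, HAND2, GATA3 and SOX2. Probe sets named as open reading frames or LOC genes were passed over. Other genes are named as examples chosen after their values were seen, and the text says where. A gene of the G1/S and DNA replication list that the rule takes is not reported here.

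The model was tested on simulated arrays with the real levels of the 10946 genes, 200 of them changed. With the array medians shifted as in the data, centred arrays recovered 68.7%, 95.5% and 98.5% of changes of 0.5, 1 and 2 on the log2 scale and called 6 unchanged genes. Fitted without centring, the same arrays gave calls for 99.26% of the unchanged genes, since the shift itself is then counted as a change. The simulated shift was equal for every gene, so centring removes it by construction. In the data the shift depended on level, with medians of 0.34 in decile 5 of all genes and 0.59 in decile 9. The simulation therefore gives no rate of false calls for the fit relative to the median gene. In simulated lists of 40 genes, camera called 2 of 2 raised lists and 0 of 26 unchanged lists. Genes were simulated without correlation between members of a list. In the data the estimated correlations of lists ranged from 0.21 to 0.853 as deposited and from -0.162 to 0.473 on centred arrays. These counts therefore give no rate of false calls by camera for lists whose genes are correlated.

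Alternatives fixed before the data were examined were quantile normalization, centring on array medians or on ERCC probe sets, other filters and pseudocounts, other variance models, the mean of a gene's probe sets, the replicate number as a block, leaving out each array, an estimated correlation in camera, and an adjusted p threshold of 0.01. Alternatives added after seeing the data were centring on the median deviation of ERCC probe sets, the cancer-testis list without CTCFL, an estimated correlation on centred arrays, level-matched lists on quantile-normalized values, a test against a minimum change of 0.2, and each CTCFL probe set in turn. The number of arrays, 2 per group, limits the precision of every value.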

Results

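The data were 4 array profiles of TAE684-resistant Kelly neuroblastoma cells, 2 from cells carrying the hairpin against BORIS and 2 from cells carrying the luciferase hairpin. Across the 10946 genes tested, log2 intensities correlated at 0.9968 between the shBORIS replicates and at 0.9963 between the shLUC replicates, and at 0.9597 to 0.9609 across the groups. These correlations are across genes, which are not independent replicates. No probe set had an identical value on both replicates of a group. The ratio of the GAPDH control probe sets at the transcript's 2 ends, a measure of RNA integrity, was 0.999 and 0.974 on the shBORIS arrays and 0.994 and 0.95 on the shLUC arrays; that of ACTB was 1.361 and 1.321 against 1.464 and 1.381, lower on both shBORIS arrays. The comparison asks which transcripts differ when BORIS is reduced in cells that have become resistant to ALK inhibition. The labels name no other hairpin against BORIS. Effects of this hairpin on other genes therefore cannot be told apart from effects of reduced BORIS.

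The targeted gene, CTCFL, was 4.74-fold lower in shBORIS cells. Its brightest probe set had an intensity of 719 ± 25.7 (SD, n = 2) with shBORIS and 3470 ± 133 (SD, n = 2) with shLUC, a log2 difference of -2.25 (SE 0.11; limma adjusted p = 1.8e-92). Of 7 probe sets that named CTCFL alone, 5 fell, by 2.39-fold to 8.29-fold. The dimmest was higher by 0.39 as deposited (adjusted p = 0.00165) but -0.09 relative to the median gene (adjusted p = 0.429). The last differed by 0.11 (adjusted p = 0.404), and fell by 0.36 relative to the median gene (adjusted p = 0.00568). A probe set shared with another gene was not used.

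**Figure D1:**
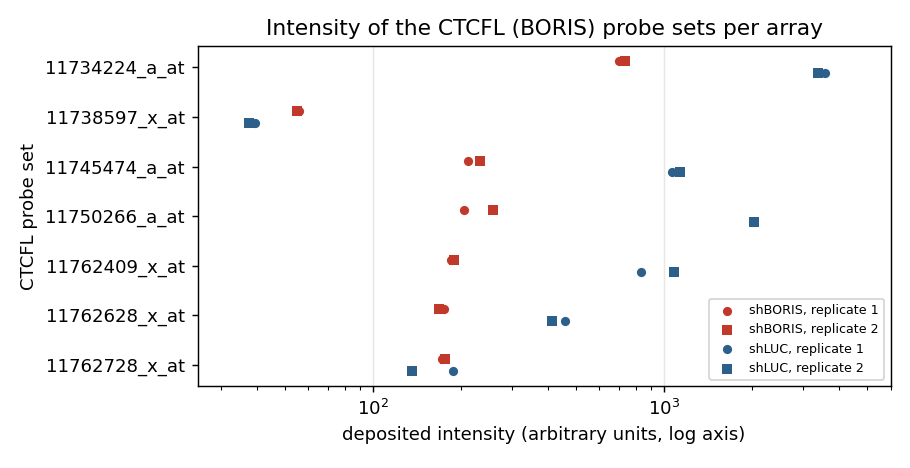
Deposited intensity (arbitrary units, log axis) of the 7 CTCFL probe sets on each array, with shBORIS in red and shLUC in blue and circles and squares for replicates 1 and 2. In 5 probe sets both shBORIS arrays lie below both shLUC arrays; the dimmest probe set lies the other way as deposited, by 0.39 on the log2 scale, and reads -0.09 relative to the median gene, and in the probe set at the bottom the shBORIS arrays lie between the shLUC arrays.

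Most transcripts were brighter in shBORIS cells on the deposited scale. As deposited, 8452 of the 10946 genes were higher and 504 lower, so that 94.4% of the called genes were higher, and 723 rose and 36 fell at least 2-fold. The median gene differed by 0.48 on the log2 scale, from 0.04 in the dimmest decile of all genes to 0.59 in the ninth decile and 0.53 in the brightest. Relative to the median gene, 3307 genes rose and 3161 fell (51.1% of calls higher), with 39 rises and 181 falls of at least 2-fold. After quantile normalization the counts were 2911 and 3125. All 3307 relative rises were also higher as deposited, and 504 genes were lower both ways, but 693 genes changed from higher to lower when the arrays were centred. Without shLUC replicate 1, 313 genes were lower as deposited in place of 504.

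**Figure D2:**
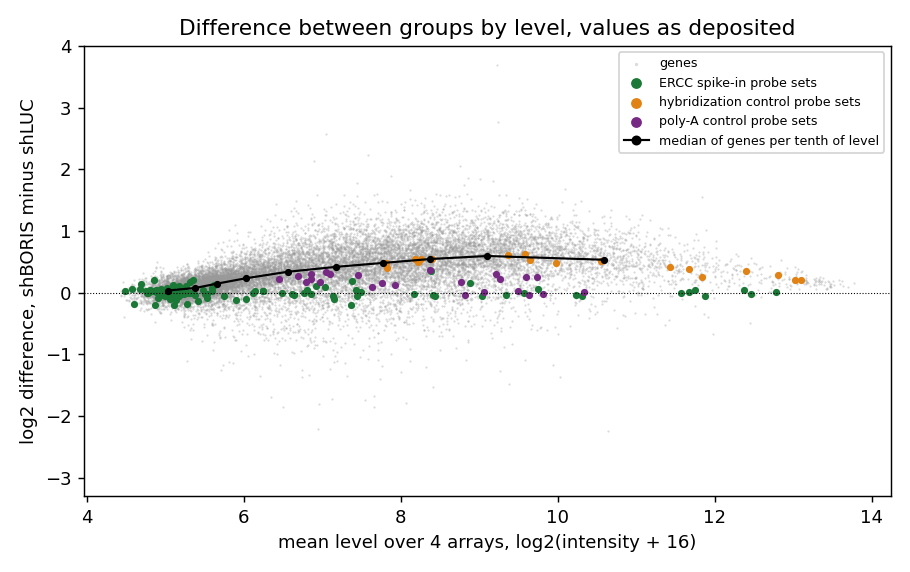
Log2 difference between groups (shBORIS minus shLUC, as deposited) against mean level over the 4 arrays as log2(intensity + 16), with genes in grey, 3 kinds of control probe sets in colour and the black line joining medians per decile of level. The line climbs from 0.04 to 0.59, the ERCC probe sets lie around 0 and the hybridization controls have a median of 0.49; centring or quantile normalization brings the median gene to 0.

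The largest rise was that of TXNIP, which binds and inhibits thioredoxin and responds to glucose. Its intensity was 2144 ± 80.7 (SD, n = 2) with shBORIS and 151 ± 1.13 (SD, n = 2) with shLUC, 12.9-fold as deposited and 9.27-fold relative to the median gene (log2 3.21, SE 0.06; limma adjusted p = 9.31e-10), and all 5 of its probe sets had the same sign. SNX5, a sorting nexin of endosomal transport, rose by 2.30 relative to the median gene (SE 0.05). The small nucleolar RNA SNORD17 rose by 2.10 from a shLUC intensity near background, so the size is approximate, and it lies inside SNX5, so its probe set cannot be assigned with certainty. LIN28A, an RNA-binding protein of stem cells, rose by 1.76. EGR1, an immediate early transcription factor, rose by 1.66, also approximate, from a shLUC intensity of 40.9. HTR3A, a serotonin-gated channel subunit, rose by 1.57. PPP2R1B, a scaffold subunit of a protein phosphatase, PHTF2, NRBP1 and the cytokinesis protein ANLN rose by 1.42, 1.38, 1.36 and 1.34.

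After CTCFL, which fell by 2.72 relative to the median gene, the largest fall was that of ZCCHC12, from an intensity of 249.8 to 41.5, a log2 change of -2.68 (SE 0.08; limma adjusted p = 3.16e-08). APOC2, a cofactor of lipoprotein lipase, fell by 2.34, and SLC27A2, which activates fatty acids, fell by 2.33. The secreted Wnt antagonist SFRP5 fell by 2.28, the orphan receptor GPR160 by 2.27 (log2 -2.27) and the GTPase-activating protein ARHGAP9 by 2.21 (log2 -2.21). The matrix protease MMP9 fell by 2.16. The shBORIS intensities of ZCCHC12, SFRP5, APOC2, TUBB8 and CGB1 lay under the filter's 61.4, and those of ZCCHC12, APOC2 and TUBB8 close to or below the mean of background probe sets, so the size and order of these falls are approximate. CGB1 at -2.20 and TUBB8 at -2.17 have near-identical paralogs and are uncertain.

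**Figure D3:**
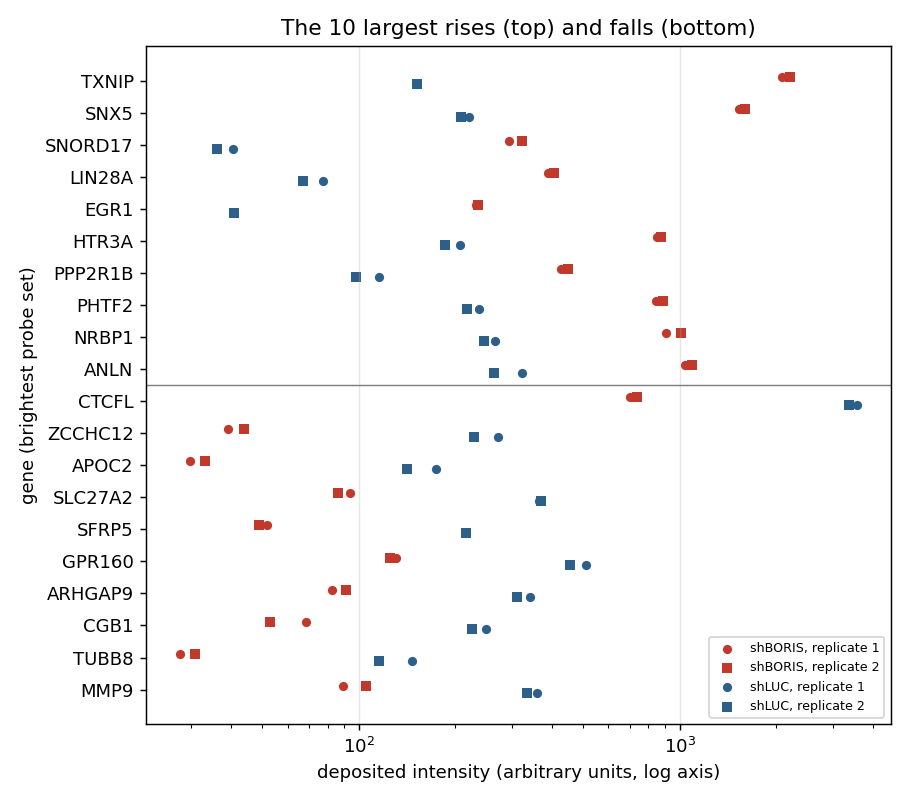
Deposited intensity (arbitrary units, log axis) of the 10 genes with the largest rise and the 10 with the largest fall on each array, by brightest probe set, with shBORIS in red and shLUC in blue and circles and squares for replicates 1 and 2. The arrays of the groups do not overlap for any of the 20 genes, and TXNIP shows the widest gap, 2144 against 151.

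Cell cycle genes rose together. Of 59 tested genes of G2/M and mitosis, 54 rose relative to the median gene and 0 fell, with a median of 0.45. The cytokinesis gene ANLN rose by 1.34, the transcription factor FOXM1 by 1.13, the condensin subunit NCAPG by 1.10 and the spindle motor KIF11 by 1.04; CDK1, chosen after its value was seen, rose by 0.61. Of 47 genes of G1/S and DNA replication, 41 rose and 0 fell, with a median of 0.55. The helicase subunit MCM5 rose by 1.04, the ribonucleotide reductase subunit RRM2 by 1.01 and the helicase BLM by 0.97. Cyclin E (CCNE1), also chosen after its value was seen, rose by 0.85. Both lists passed camera (adjusted p = 9.47e-15 for G2/M and 2.68e-14 for G1/S). Neither passed with correlation estimated from the arrays (adjusted p = 0.963 with an estimated correlation as deposited, and adjusted p = 0.166 with an estimated correlation on centred arrays). On centred arrays the estimates were -0.006 for G2/M and -0.009 for G1/S, under the preset 0.01. Correlation between members therefore does not account for the loss of the call there. That form of camera has 2 residual degrees of freedom, so it can decide little here.

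Genes of CTCF and cohesin architecture, the factors that fold the genome into loops, were also higher. Relative to the median gene, 15 of 24 rose and 2 fell, with a median of 0.24. As deposited, the camera adjusted p was 0.00733, and 0.963 with an estimated correlation. It was 0.0636 with a filter at the 60th percentile and 0.0618 with the mean of probe sets. On centred arrays, the camera adjusted p was 0.00333, and 0.505 with an estimated correlation. There it was 0.0303 with the 60th percentile filter and 0.0165 with the mean of probe sets. The cohesin acetyltransferase ESCO2, whose transcript follows S phase, rose by 1.01, the cohesin regulators PDS5B and WAPL by 0.76 and 0.54, and CTCF itself by 0.54. The 2 that fell, chosen after their values were seen, were the transcription kinase CDK9 at -0.39 and the deacetylase HDAC8 at -0.33; as deposited they read 0.09 and 0.15.

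Genes of the unfolded protein and integrated stress response were lower than other genes. Of 40 tested, 25 fell relative to the median gene and 4 rose, with a median of -0.30. As deposited, the camera adjusted p was 5.97e-04, 0.963 with an estimated correlation and 0.0506 with no filter. On centred arrays, the camera adjusted p was 3.27e-04, 0.505 with an estimated correlation and 0.0207 with no filter. The stress transcription factor DDIT3 (CHOP) fell by 1.62, from an intensity of 217 to 89.3. Among members chosen after their values were seen, HERPUD1, which acts in degradation at the endoplasmic reticulum, fell by 1.12, the transcription factor ATF3 by 1.00, the chaperone HSPA5 (BiP) by 0.92, DDIT4 by 0.79 and the chaperone HYOU1 by 0.77. The 4 that rose were CEBPG at 0.44, the serine synthesis enzymes PSAT1 and PHGDH at 0.26 and 0.20, and SEL1L at 0.20. Only 1 of the 2 CEBPG probe sets above the filter had this sign. PHGDH did not pass without shBORIS replicate 2 (adjusted p = 0.104), nor SEL1L without shLUC replicate 2 (adjusted p = 0.101) or shBORIS replicate 1 (adjusted p = 0.0562), and SEL1L read -0.10 relative to the median gene as the mean of its probe sets. As deposited, the list's median was 0.18, with 17 members higher and 6 lower.

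Cytosolic ribosomal protein genes moved less than other genes. As deposited their median was 0.17 with 24 of 46 higher and 1 lower, while relative to the median gene it was -0.31 with 0 higher and 45 lower, and after quantile normalization it was -0.02. RPS9 fell by 1.15 relative to the median gene and by 0.67 as deposited. RPL14 and RPS6 read 0.34 and 0.30 as deposited, -0.14 and -0.18 relative to the median gene, and 0.12 and 0.09 after quantile normalization. On centred arrays with no filter they read -0.03 and -0.06 and did not pass (limma adjusted p = 0.663 and 0.284). RPL14 read 0.012 as the mean of its probe sets on centred arrays. RPL7, the member not called, read 0.43 as deposited and -0.04 relative to the median gene. The list passed camera as deposited (adjusted p = 0.0022) and on centred arrays (adjusted p = 5.49e-13, and 3.88e-21 to 3.95e-08 without each array in turn). As deposited it did not pass without shBORIS replicate 1 (adjusted p = 0.957) or replicate 2 (adjusted p = 0.0662) or with no filter (adjusted p = 0.0815), and it did not pass after quantile normalization (adjusted p = 0.435) or with an estimated correlation (adjusted p = 0.963 as deposited and 0.505 on centred arrays). Ribosomal protein genes have many processed copies, so single members are uncertain.

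Genes of the mesenchymal state of neuroblastoma, a migratory state with features of connective tissue, went both ways. Of 26 tested, 13 fell and 6 rose relative to the median gene, with a median of -0.21; as deposited the median was 0.26. The intermediate filament gene VIM fell by 1.69 and the collagen gene COL5A1 by 1.55. Among members chosen after their values were seen, the AP-1 subunit JUN fell by 1.17, COL1A1 by 1.11, COL6A3 by 1.05, THBS1 by 0.93 and NOTCH3 by 0.82. The cytokine receptor IL6ST rose by 0.80 and the transcription factor SNAI2 by 0.56. Markers of other cell types were also lower more often than higher. Of 7 Schwann cell and glial markers 5 fell and 1 rose, with a median of -0.40, and of 7 fibroblast, endothelial and immune markers 4 fell and 1 rose, with a median of -0.27; both medians were above 0 as deposited (0.08 and 0.20). NGFR fell by 0.77, APOE (chosen after its value was seen) by 0.61 and the smooth muscle actin ACTA2 by 1.06, while the surface marker THY1 rose by 0.65. The mesenchymal list passed camera as deposited (adjusted p = 0.00415; adjusted p = 0.963 with an estimated correlation), but not with no filter (adjusted p = 0.0506), after quantile normalization (adjusted p = 0.142) or on centred arrays (adjusted p = 0.092, 0.0429 without shBORIS replicate 2 and 0.0195 with the mean of probe sets). The marker lists did not pass (adjusted p = 0.0691 and 0.292), but the list of Schwann cell and glial markers did without shBORIS replicate 2 or shLUC replicate 2 (adjusted p = 0.0484 and 0.0471), with no filter (adjusted p = 0.00872) or with ERCC centring (adjusted p = 0.0286; adjusted p = 0.963 with an estimated correlation on all arrays).

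Of 8 cancer-testis antigen genes tested, 5 fell relative to the median gene and 1 rose, with a median of -0.31. The 5 include CTCFL itself, the target of the hairpin. The others, chosen after their values were seen, were MAGEA12 at -0.41, CTAG2 at -0.33, PRAME at -0.32 and MAGEC1 at -0.29, which read 0.06, 0.15, 0.16 and 0.18 as deposited, none of these past the threshold. MAGEA10 rose by 0.25. MAGEC2 at 0.17 and MAGEA1 at 0.02 did not pass. The list passed camera as deposited (adjusted p = 0.00733; adjusted p = 0.963 with an estimated correlation) and not on centred arrays (adjusted p = 0.202), after quantile normalization (adjusted p = 0.126) or with ERCC centring (adjusted p = 0.13). The call rested on CTCFL, since the other 7 members did not pass, as deposited (adjusted p = 0.631) or on centred arrays (adjusted p = 0.44). Members of the MAGE and CTAG families have near-identical paralogs and are uncertain.

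Genes of the adrenergic state, the neuron-like state defined by a core set of transcription factors, split evenly relative to the median gene, with 11 of 31 higher, 12 lower and a median of -0.02, against 23 higher and 1 lower as deposited (camera adjusted p = 0.795). CHGA, a secretory granule protein, rose by 1.07, the receptor RET by 0.85, DACH1 by 0.68 and HAND1 by 0.46. Chosen after their values were seen, SOX11 fell by 1.15, PHOX2A by 0.65 and INSM1 by 0.51, while DBH, which makes noradrenaline, rose by 0.39. As deposited PHOX2A and INSM1 read -0.17 and -0.03 and did not pass (limma adjusted p = 0.145 and 0.786). MYCN read 0.15 as deposited (limma adjusted p = 0.11) and fell by 0.33 relative to the median gene (adjusted p = 2.01e-04) and by 0.11 after quantile normalization. HAND2 read 0.16 as deposited (adjusted p = 0.0782) and fell by 0.31 relative to the median gene and by 0.13 after quantile normalization. MYCN and HAND2 are bright, at intensities of 5313 and 4940 with shLUC. Random lists as bright as the ribosomal protein genes had a typical median of -0.26 relative to the median gene. Much of the relative fall of MYCN and HAND2 may thus come with level, which was not tested for single genes. GATA3 was higher by 0.32 as deposited and fell by 0.15 relative to the median gene, and SOX2 rose by 0.24 relative to the median gene. The relative calls of GATA3 and SOX2 were lost without shLUC replicate 2 (adjusted p = 0.222 and 0.0895), and that of GATA3 also without shBORIS replicate 2 (adjusted p = 0.263).

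ALK, the target of the drug, rose by 0.96 relative to the median gene (SE 0.08; limma adjusted p = 5.29e-06), from an intensity of 86.4 ± 2.60 (SD, n = 2) to 262 ± 30.8 (SD, n = 2). Of 31 components of the ALK, receptor tyrosine kinase and PI3K pathways, 6 rose and 15 fell, against 18 higher and 4 lower as deposited, with a median of -0.18 that was 0.29 as deposited. The exchange factor SOS1 rose by 0.70. The receptor IGF1R fell by 0.92, its adaptor IRS1 by 0.83 and FGFR4 by 0.76 (chosen after their values were seen). The list did not pass camera as deposited (adjusted p = 0.165) or on centred arrays (adjusted p = 0.0519) and passed after quantile normalization (adjusted p = 0.0301) and with ERCC centring (adjusted p = 0.0441); with an estimated correlation the adjusted p was 0.963 as deposited and 0.505 on centred arrays. Of 25 genes of receptor tyrosine kinase and MAPK feedback output, 6 rose and 13 fell, against 15 higher and 2 lower as deposited (camera adjusted p = 0.75, and 0.308 on centred arrays). EGR1 rose by 1.66, cyclin D (CCND1) by 0.95, FOS by 0.36 and PHLDA1 by 0.32. Chosen after their values were seen, EPHA2 fell by 0.87 and DUSP5 by 0.79, and the MAPK inhibitors DUSP6 and SPRY4 fell by 0.42 and 0.44 but read 0.06 and 0.04 as deposited.

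Among the developmental lists, 14 of 28 neural crest and neural progenitor factors rose and 6 fell, and 24 were higher and 1 lower as deposited (adjusted p = 0.325), led by ID1 at 1.03, LIN28B at 0.79 and ID3 at 0.70. Of 38 genes of neuronal differentiation and synapse, 10 rose and 17 fell, against 22 higher and 0 lower as deposited (adjusted p = 0.733, and 0.313 on centred arrays); the neurofilament genes INA and NEFH rose by 0.90 and 0.85, while NEFM and NEFL, chosen after their values were seen, fell by 0.53 and 0.31 (-0.06 and 0.17 as deposited, not past the threshold). Of 25 targets of Notch, Wnt, Hedgehog and TGF-beta signalling, 5 rose and 11 fell, against 15 higher and 2 lower as deposited (adjusted p = 0.233), and LTBP2, which binds the extracellular matrix, fell by 1.72. Of 13 HOX genes 5 rose and 2 fell, with 11 higher and 0 lower as deposited (adjusted p = 0.795), with HOXC8 at 0.82. Of 13 imprinted genes 5 rose and 6 fell, against 9 higher and 1 lower as deposited (adjusted p = 0.795), with the growth inhibitor CDKN1C at -1.22 and MKRN3 at 0.68. The median and the mean had opposite signs for HOX genes (-0.07 and 0.02), adrenergic genes (-0.02 and 0.0031) and replication-dependent histones (0.01 and -0.09). Camera's direction turned with the scaling for adrenergic, oxidative phosphorylation, imprinted and histone genes.

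Among the stress and survival lists, 11 of 26 p53 targets fell and 4 rose, against 17 higher and 2 lower as deposited (adjusted p = 0.283), with ZMAT3 at 0.33 and GADD45A, chosen after its value was seen, at -1.05. Of 21 apoptosis regulators 4 rose and 6 fell, against 16 higher and 1 lower as deposited (adjusted p = 0.585), with BID at 0.21 (0.08 after quantile normalization). Of 17 interferon response genes 1 rose, B2M at 0.26, and 8 fell, against 11 higher and 3 lower as deposited (adjusted p = 0.0529); the interferon response list passed without shBORIS replicate 1 or 2 (adjusted p = 0.0155 and 0.0404), with no filter (adjusted p = 0.00729) and with ERCC centring (adjusted p = 0.0495), but not on centred arrays (adjusted p = 0.0998), after quantile normalization (adjusted p = 0.266) or with an estimated correlation (adjusted p = 0.963). Of 20 genes of the heat shock response 6 rose and 6 fell, against 16 higher and 2 lower as deposited (adjusted p = 0.795), with CHORDC1 at 0.72 and the chaperone HSP90AA1 at 0.54. Of 21 NRF2 targets 2 rose and 10 fell, against 15 higher and 0 lower as deposited (adjusted p = 0.551), with NQO1 at 0.31. Of 10 genes of drug efflux and detoxification 3 fell, led by the transporter ABCA3 at -1.17, and 1 rose, against 8 higher and 1 lower as deposited (adjusted p = 0.292, and 0.0287 with no filter). The riser was GSTP1 at 0.21, which did not pass without shLUC replicate 1 (adjusted p = 0.113) or shBORIS replicate 2 (adjusted p = 0.0688).

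Among the metabolic and growth lists, 14 of 39 MYC target and ribosome biogenesis genes rose and 10 fell, against 34 higher and 1 lower as deposited (adjusted p = 0.551, and 0.0102 with no filter), with UTP20 at 0.59 and nucleolin (NCL, chosen after its value was seen) at -0.87. Of 33 genes of hypoxia and glycolysis 6 rose and 17 fell, against 23 higher and 1 lower as deposited (adjusted p = 0.551), with ADM at 0.54. Of 21 genes of cholesterol synthesis and uptake 3 rose and 9 fell, against 16 higher and 1 lower as deposited (adjusted p = 0.373), with ACAT2 at 0.68 and TM7SF2 at -1.17. Of 33 genes of oxidative phosphorylation 7 rose and 10 fell, against 31 higher and 0 lower as deposited (adjusted p = 0.847), with NDUFA10 at 0.36. Of 6 replication-dependent histones 0 rose and 2 fell relative to the median gene (adjusted p = 0.795), while 5 were higher and 1 lower as deposited. H4C3 read 0.34 as deposited and -0.14 relative to the median gene. On centred arrays with no filter it read -0.02 and did not pass (limma adjusted p = 0.662).

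Other genes that the rule takes from the lists were, except for HLA-C, all higher as deposited, by 0.24 to 1.30. Relative to the median gene GDAP1 and SYT4 rose by 0.83 and 0.78, UBE3A by 0.59, DNAJB6 by 0.51, BNIP3L and MEIS2 by 0.46, HSPH1 by 0.45, IGF2R by 0.44 and PPAT by 0.43. NOP58 and PIK3R1 rose by 0.40, HOXD3 by 0.39, TRIAP1 by 0.35, MSMO1 by 0.33, KDM3A by 0.32, POLR1A by 0.31, NDUFS3 and NDUFA9 by 0.29, DDB2 and ATP5PB by 0.25 and GPI by 0.23. As the mean of their probe sets PIK3R1, DNAJB6 and ATP5PB read -0.0068, -0.13 and 0.05 and did not pass.

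Calls of some of these genes were lost without 1 array. BAK1 rose by 0.29, INSIG1 and GSR by 0.25, HOXD1 and HEY1 by 0.24, HOXC6 by 0.23, MDM2 and BAD by 0.19 and CASP6 and CNP by 0.17, while POU3F1 fell by 0.23 (0.24 as deposited) and HLA-C by 1.15 (-0.67 as deposited). Without shBORIS replicate 1 the adjusted p was 0.0844 for POU3F1, 0.0887 for BAK1, 0.12 for CASP6, 0.181 for INSIG1, 0.191 for HOXD1, 0.0514 for HOXC6 and 0.282 for HEY1. Without shBORIS replicate 2 it was 0.151 for CNP, 0.17 for MDM2, 0.132 for CASP6, 0.0912 for BAD and 0.0874 for GSR. Without shLUC replicate 1 it was 0.0646 for POU3F1, 0.088 for MDM2, 0.0852 for BAK1, 0.0751 for CASP6, 0.141 for BAD, 0.0631 for HOXD1 and 0.58 for HLA-C. Without shLUC replicate 2 it was 0.0646 for MDM2, 0.126 for CASP6, 0.268 for HEY1 and 0.475 for HLA-C. CNP, CASP6, BAD, GSR, INSIG1, HOXC6 and HEY1 did not pass after quantile normalization, and MDM2 read -0.04 as the mean of its probe sets. INSIG1 read 0.10 as the mean of its probe sets and did not pass. GFAP at -0.14, PDGFRB at -0.0505, TYROBP at -0.13, PRDX1 at -0.026, CYP1B1 at -0.009, IFIT5 at 0.17, IRF7 at 0.16, SOD2 at 0.12, ABCC4 at 0.14, H2BC5 at 0.19, H2AC20 at 0.14 and H2AC6 at 0.023 were not called relative to the median gene. After quantile normalization GFAP and PRDX1 read 0.018 and 0.16, and PRDX1, IFIT5 and H2BC5 passed.

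Counts of members above are over all genes tested, relative to the median gene unless stated, and the camera p-values beside them are as deposited unless stated. On centred arrays the 23 lists that did not pass had adjusted p-values of 0.0519 to 0.861. The relative counts adjusted over the list alone were the same except for ALK and receptor tyrosine kinase components (6 and 17), apoptosis regulators (3 and 6), oxidative phosphorylation (6 and 10) and Notch, Wnt, Hedgehog and TGF-beta targets (5 and 12). As deposited other lists differed, such as ribosomal proteins, with 16 called over the list alone against 24 higher and 1 lower over all genes. Of the 28 lists, 7 passed camera as deposited and 5 on centred arrays, and 0 passed with an estimated correlation on either scale, where 0 and 2 lists had an unadjusted p under 0.05. Fry passed 0 lists as deposited and 20 on centred arrays after adjustment.

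**Figure D4:**
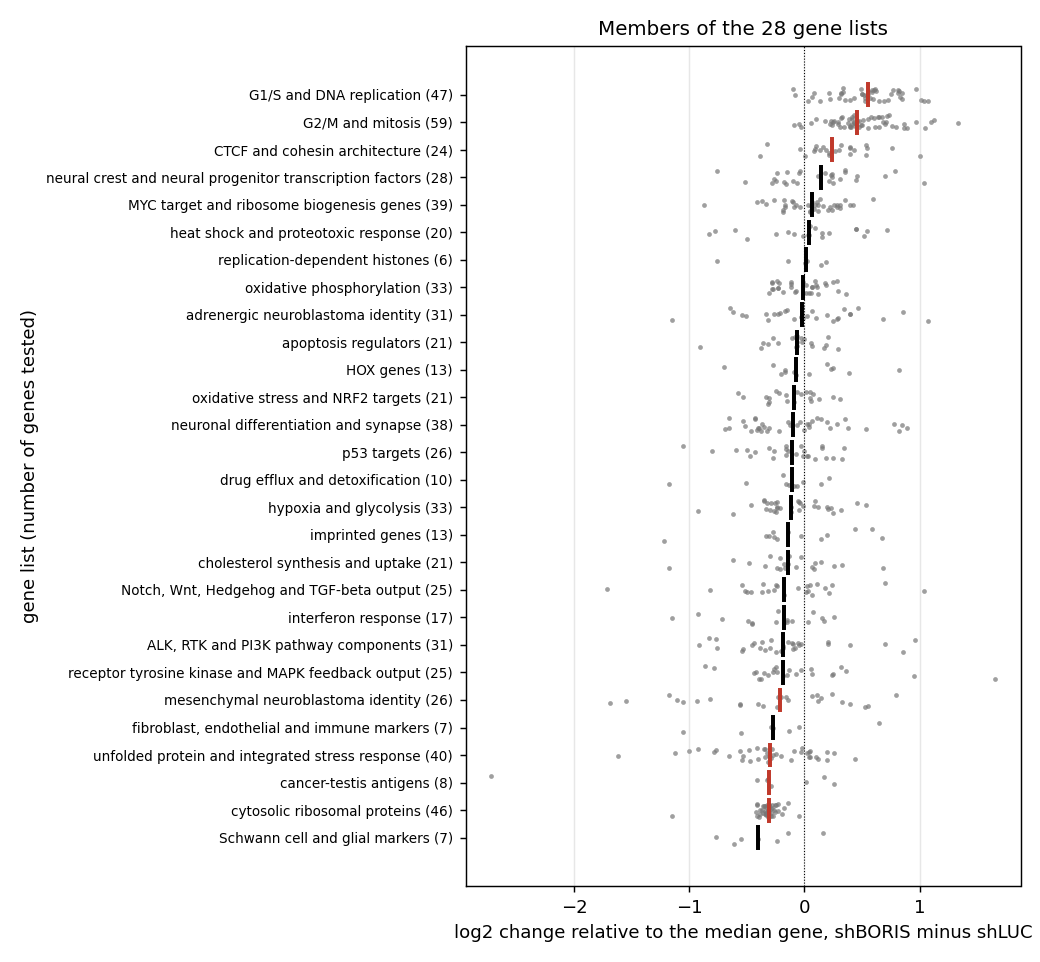
Log2 change relative to the median gene (shBORIS minus shLUC) of each tested member of the 28 gene lists, with the number tested in brackets and a bar at each list's median, red for the 7 lists that passed camera as deposited. The cell cycle lists lie highest, at medians of 0.55 and 0.45; medians of lists below 0 here, such as ribosomal proteins at -0.31, were above 0 as deposited (0.17), and ribosomal proteins read -0.02 after quantile normalization.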

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

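The tests on control probe sets in this part were chosen after the difference between the groups had been seen.

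Some control probe sets that belong to no gene also differed between the groups. The 18 hybridization control probe sets (bioB, bioC, bioD and cre), bacterial transcripts added after labelling, were all higher in shBORIS, with a median log2 difference of 0.49 and mean levels of 10.42 and 10.47 on the shBORIS arrays against 10.03 and 9.99 on the shLUC arrays. The 23 probe sets for background by GC content had a median difference of 0.0354, with mean levels of 5.76 and 5.82 against 5.63 and 5.64. They stand out because both shBORIS arrays lay above both shLUC arrays in data that no comparison of genes used. The 3 probe sets for 18S ribosomal RNA had a median difference of -0.26, which was -0.19 without shLUC replicate 1 and -0.54 without shLUC replicate 2, and the 17 tag controls one of -0.0202, with 7 higher.

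The pattern to explain is that the median gene was higher in shBORIS by 0.48 as deposited, while the ERCC probe sets differed by -0.0018. More cellular RNA loaded on the shBORIS arrays would leave the hybridization controls level on unscaled values, since they join after labelling. With scaling to the ERCC RNAs, which were labelled with the sample, it would leave them level or lower. The hybridization controls rose by 0.4862, close to the 0.51 of genes of the same level, which argues against loading as the whole cause. Less spike-in relative to all other RNA, if the values were scaled to it, could raise cellular genes, hybridization controls and poly-A controls alike. The rise of the hybridization controls goes with this. Yet the 24 poly-A control probe sets differed by 0.196 where genes of the same level differed by 0.51. Their kinds disagreed, with dap at 0.26, lys at -0.0035 and mean thr levels of 7.90 and 6.91 on the shBORIS replicates. The 17 tag controls and the 3 probe sets for 18S ribosomal RNA did not rise either, at -0.0202 and -0.26. A single scaling factor would raise all probe sets alike. Less spike-in thus stays open for at most part of the shift. More RNA per cell under the BORIS hairpin might give the same 0.4771, but it cannot be told apart from a difference in spike-in, because the amount of spike-in per cell is not given in the sources used here. If the scale was set by the spike-ins, which no label states, the direction of most single genes as deposited therefore rests on them.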

How the results depend on the processing

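The treat test, the ERCC centring by median deviation, the estimated correlation on centred arrays, the cancer-testis list without CTCFL and the CTCFL probe sets in turn were chosen after the data were seen; the other alternatives were planned. Of 2679 comparisons of 171 named genes with an alternative, 2538 kept direction and side of the threshold, 63 lost the call, 19 gained it, 41 turned with a call in either setting and 18 changed sign with a call in neither. For the 28 lists, 395 of 446 were kept, 14 lost, 12 gained, 1 turned with a call and 24, in 11 lists, changed direction without one. CTCFL kept its fall in every setting that used its brightest probe set (-2.28 to -2.21 on leaving out an array) and at -1.50 as the mean of its probe sets; single probe sets read 0.39 and 0.11. The probe set at 0.39 had mean intensities of 55.3 with shBORIS and 38.6 with shLUC, under the filter's 61.4. Signal near background compresses differences. That at 0.11 had mean intensities of 175 with shBORIS and 162 with shLUC, above the filter, so dimness does not account for it. The cause was not tested.

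Scaling decided the counts by construction, since it sets the level of the median gene. Higher and lower genes numbered 8452 and 504 as deposited, 2911 and 3125 after quantile normalization, 3307 and 3161 with arrays centred on medians, and 7213 and 1041 centred on the median level of the 33 brighter ERCC probe sets. At 2-fold these were 723 and 36, 38 and 176, 39 and 181, and 298 and 57, with a global shift of 0.48, -0.0018, 3e-04 and 0.32. The ERCC median level differed by 0.16 between the groups because it fell on 3 different probe sets over the 4 arrays, while the median of the 33 differences was -0.0115. Centred on the median deviation of those probe sets, 8399 genes were higher and 480 lower with a shift of 0.48. A minimum change of 0.2 on centred arrays left 1491 and 1573.

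The global shift was 0.28 without a filter, 0.54 with a filter at the 60th percentile, 0.52 and 0.39 with pseudocounts of 1 and 64, and 0.42 with the mean of probe sets; no filter adds dim genes, which differ less. The 60th percentile filter, which tests fewer genes, gave 275 lower and 20 at least 2-fold lower. A pseudocount of 64, which compresses folds, gave 339 and 20 genes at 2-fold, and the mean of probe sets 431 higher at 2-fold; the cause of the last was not tested. Lists past the threshold fell from 7 to 0 as deposited and from 5 to 0 on centred arrays with an estimated correlation. Camera then takes its p from 2 residual degrees of freedom, and the estimates ranged from 0.21 to 0.853 as deposited and from -0.162 to 0.473 on centred arrays.

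Leaving out each array gave 7283 to 8359 higher, 313 to 486 lower (313 without shLUC replicate 1), 555 to 984 and 29 to 45 at 2-fold, 7 to 8 lists and a shift of 0.43 to 0.53; an arm of 1 array is assumed to vary like the other. On centred arrays, 20 of 157 called named genes lost the call on leaving out some array and 0 turned. The list: cytosolic ribosomal proteins, lower by camera as deposited, had an adjusted p of 3.23e-06 to 0.957 and turned to higher at the last, without shBORIS replicate 1; the cause was not tested. As deposited, HLA-C ranged from -0.73 to 0.45 and turned to 0.45 and 0.32 without shLUC replicate 1 or 2, where another probe set became the brightest. NOTCH3, at -0.34 as deposited, read 0.0265 as the mean of its probe sets, also as deposited. The median gene read 0.42 in that setting, so NOTCH3 stayed below it. The cause of the turn was not tested.

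With a replicate block, 7617 genes were higher and 378 lower as deposited, and 7 lists passed. The numbers are shared by 2 pairs only, no label ties them to a day, and deviations of same-numbered arrays correlated at 0.098 across genes. With 2 pairs this neither shows nor excludes a pairing of same-numbered arrays. On centred arrays 3438 genes rose and 3236 fell with the block, against 3307 and 3161 without it. There 0 of the 157 called named genes lost the call under the block.

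The named genes that turned with a call in either setting, other than HLA-C and NOTCH3 above, did so with the global shift removed. After quantile normalization these were POU3F1 at -0.23, PDGFRB at -0.080, TYROBP at -0.062, MAGEA1 at -0.082, CYP1B1 at -0.032, MYCN at -0.11, HAND2 at -0.13, GATA3 at -0.22, CDK9 at -0.44, HDAC8 at -0.31, PRAME at -0.33, MAGEA12 at -0.40, CTAG2 at -0.27, DUSP6 at -0.39, SPRY4 at -0.27 and NEFL at -0.36. With arrays centred on medians they were GFAP at -0.14, POU3F1 at -0.23, PDGFRB at -0.0505, TYROBP at -0.13, PRDX1 at -0.026, RPL7 at -0.044, RPL14 at -0.14, RPS6 at -0.18, H4C3 at -0.14, CYP1B1 at -0.009, MYCN at -0.33, HAND2 at -0.31, GATA3 at -0.15, CDK9 at -0.39, HDAC8 at -0.33, PRAME at -0.32, MAGEA12 at -0.41, CTAG2 at -0.33, MAGEC1 at -0.29, DUSP6 at -0.42, SPRY4 at -0.44 and NEFL at -0.31.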

Other observations

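The symbol families, the level-matched lists and the scaling tests in this part were chosen after results had been seen; the tests of gene span and of neighbouring genes were set down before their results.

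Among 126 families of genes that share a symbol stem and have at least 10 tested members, 12 passed camera on centred arrays. Collagen genes fell relative to the median gene, with 14 of 18 lower, 0 higher and a median of -0.45 (camera adjusted p = 2.95e-04), and COL13A1 fell by 1.81. The DUSP phosphatases, many of which switch off MAP kinases, fell in 11 of 19 with 0 higher (median -0.29, camera adjusted p = 0.0449), among them DUSP5 by 0.79 and DUSP9 by 0.77. Solute carriers fell more often than they rose, 89 against 34 of 205 (median -0.13, camera adjusted p = 0.04), with the sialic acid transporter SLC17A5 at -1.34 and the inositol transporter SLC5A3 at 0.86. These families kept the sign of their median after quantile normalization (-0.42, -0.31 and -0.12), but as deposited their medians were 0.02, 0.19 and 0.34. COL13A1, DUSP5, DUSP9 and SLC17A5 were lower as deposited too. With an estimated correlation none of the 126 families passed (2 had an unadjusted p under 0.05; adjusted p = 0.714 with an estimated correlation for these families).

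Families of the large mitochondrial ribosomal subunit, of mRNA turnover and of the nuclear pore were higher, as deposited and relative to the median gene. Of 49 MRPL genes 27 rose and 5 fell (median 0.22, 0.13 after quantile normalization, camera adjusted p = 0.00248), with MRPL1 at 1.10, whereas the 28 MRPS genes of the small subunit did not pass (12 rose, 4 fell, camera adjusted p = 0.264). Of 11 CNOT genes, which form a deadenylase complex, 10 rose and 0 fell (median 0.33, 0.29 after quantile normalization, camera adjusted p = 0.0125), with CNOT2 at 0.87. Of 22 nucleoporin genes 16 rose and 3 fell (median 0.25, 0.16 after quantile normalization, camera adjusted p = 0.0374), with NUP50 at 1.06. The adjusted p was 0.714 with an estimated correlation for MRPL, CNOT and NUP. The other 6 families past the threshold were MCM, CEP, RBM and PHF, which were higher, and RPL and RPS, which were lower relative to the median gene but had medians of 0.17 and 0.19 as deposited and -0.0291 and 0.0087 after quantile normalization. Genes in both paragraphs were chosen after their values were seen.

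The rise of cell cycle genes was set against technical explanations. After quantile normalization the 106 genes of both cell cycle lists had a median of 0.4492, while the highest of 10000 lists of genes of the same level reached 0.14, which argues against scaling or level as the whole cause. The highest of 10000 lists matched on gene span reached 0.1214, and all 106 members had a span, which argues against gene length. A larger share of cycling cells under the BORIS hairpin is a hypothesis that may account for the rise, but cell numbers and cell cycle phases were not analysed here, and a difference in density or selection between the cultures could do the same and was not tested.

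The lower position of ribosomal protein genes was weighed in the same way. Quantile normalization, which adjusts for the smaller differences of the brightest probe sets, brought the list's median to -0.0199 from -0.31 relative to the median gene, so the choice of scaling could account for the distance from the median gene, though 1.8% of level-matched lists lay as low after that normalization. Lists of equally bright genes that left out the 46 members had a typical median of -0.26, and 0.24% of them lay as low. When members could be drawn too, which was the form of the test first run, 3.33% lay as low. Those lists partly hold the tested genes, with a typical median of -0.28, so this form cannot count against a difference. Random lists also lack the correlation between ribosomal protein genes, estimated at 0.473 on centred arrays. The level of the probe sets as the whole cause is therefore neither excluded nor shown. A biological fall of these genes stays open and untested beyond this.

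Whether neighbouring genes changed together was tested as a hypothesis, since CTCF and cohesin act over stretches of a chromosome. Over 10533 pairs of adjacent tested genes with different symbol stems, the correlation of log2 changes after quantile normalization was 0.0183 (one-sided permutation p = 0.03 from 10000 permuted orders), or 0.03% of the variance, under the 0.1 set beforehand. The correlation is across genes, which are not independent replicates, and it gives no sign of a regional change of that size.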
